A study of Mus musculus with 2 samples.

How the data were processed

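MicroRNA sequencing was done on total RNA of the left cerebral cortex of 2 male B6CASTF1/J mice aged 25 days, with 1 library per mouse, per the labels. The labels number the libraries as biological replicates 1 and 2, and the descriptions of the tissue samples give each its own animal number, while the donor entry is shared and stands for the strain. All samples thus form 1 group, and no comparison between groups was made. The deposited files hold raw read counts per gene, made by the authors on the mm10 assembly with GENCODE release M21 annotation, per the readme files. The aligner, the counting tool and their versions are not given in the sources used here. The files have no header: 4 leading entries name no gene (unmapped, multimapping, no feature and ambiguous reads), and 2202 miRNA genes follow with 3 columns of whole numbers. From the values, these columns were read as counts on both strands together, on the gene's own strand and on the opposite strand, a reading that rests on the values alone. All 2202 gene identifiers were matched to the GENCODE M21 annotation, from which symbols, positions and host genes were taken. Positions are 1-based on mm10.

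The column of own-strand counts was used throughout. It held 2388379 counts in replicate 1 and 4447390 in replicate 2, which were 44.0% and 40.3% of the mapped reads. Entries that name no gene were kept out of library sizes and tests. Of 7935381 reads in replicate 1, 31.6% were unmapped, and of 13482882 in replicate 2, 18.2%. Reads with several matches were 48.6% and 52.8% of mapped reads, and reads in no feature were 7.36% and 6.91%. Because reads with several matches were not given to genes, levels of near-identical copies are uncertain. The reference is that of C57BL/6J, so reads from the CAST/EiJ allele can mismatch it, which was not tested. At 10 counts a gene stands at 4.19 CPM in replicate 1 and 2.25 CPM in replicate 2, and the floor of 3 counts is 1.26 and 0.675 CPM.

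Counts per 1000000 (CPM) were computed here from own-strand counts, and log2 levels used a pseudocount of 1. The design, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except the alternatives that left numbered copies out of the replicate agreement and of the library comparison, which were added afterwards. Genes with at least 10 counts in each library were compared by an exact conditional binomial test, two-sided, given the library totals, with Benjamini-Hochberg adjustment at 0.05. The quasi-likelihood test of edgeR has no contrast to fit with 1 group, so edgeR 4.0.16 (R 4.3.3) served for TMM factors, for the common dispersion of the group and for an alternative exact test with that dispersion, which has 1 library on each side and no spread from other samples. DESeq2 1.42.0 gave alternative size factors. Shares have exact Clopper-Pearson intervals at 95%. The counting SE of a log2 ratio comes from the counts of the gene. Gene lists were described by their summed CPM, and by the percentile of their median log2 level among 10000 random lists of the same size. Both the medians and the random lists used genes with at least 1 count in either library, so members with no count were left out. For the difference between libraries these were matched on mean level in 6 bins, for lists with at least 3 measured genes. Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

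The genes named are the 20 with the highest mean CPM, the 4 with the highest mean CPM of each list, and, among genes with at least 100 counts in each library and an adjusted p under 0.05, the 5 with the largest log2 ratio in each direction. Mir301 and Mir26a-1 fall outside that rule, because they had under 100 counts in a library, and were added after their values were seen. Genes with numbered copies are those whose symbol ends in a hyphen and a number. Another 3 symbols of the form mmu-mir with a number also match that wording, and were left out of the list after symbols and counts were seen. A symbol on a list was matched as written or by its alternative form. The Dlk1-Dio3 symbol Mir496b lies on chromosome 19 in the annotation and had no count.

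The binomial test was tested on simulated counts drawn for the real genes and library sizes, with 393 genes tested. Of genes changed by 1.5-fold 78.4% were recovered, of genes changed by 2-fold 89.7%, and 1.51% of unchanged genes were called. The simulated counts held counting error alone and were scaled by the totals of the unchanged genes. The real libraries spread further (log2 ratio SD 0.559 against 0.0765 from counting, at 100 counts or more). The 1.51% is therefore not the rate of false calls between them. With a simulated coefficient of variation of 0.4 over 383 genes, edgeR estimated 0.373, and its exact test with that dispersion called 0 genes. Alternatives were count minimums of 1 and 100, both strands together, TMM and DESeq2 scaling, a pseudocount of 0.1, totals without the most abundant gene, numbered copies left out, and each replicate left out.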

Results

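MicroRNAs (miRNAs), short RNAs that guide repression of target mRNAs, were counted by small-RNA sequencing in the left cerebral cortex of 2 male mice aged 25 days. The mice were B6CASTF1/J, the F1 hybrid of the inbred strains C57BL/6J and CAST/EiJ. The labels give 1 group with 2 biological replicates from separately numbered males, and 1 library per mouse. The design therefore implies a description of the cortical miRNA profile and a comparison of replicate 2 with replicate 1. Each file listed raw counts for 2202 miRNA genes. Replicate 1 held 2388379 counts on the genes' own strand and replicate 2 held 4447390, which is 1.86 times as many. Levels are given as counts per 1000000 (CPM) of these own-strand counts, as the mean ± SD of n = 2 libraries unless stated otherwise. A level of 3 counts corresponded to 1.26 CPM in replicate 1 and 0.675 CPM in replicate 2. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The counts of the libraries differed by more than sampling noise in a chi-square test over 761 genes (chi-square 176676 on 760 degrees of freedom), so they were treated as separate libraries.

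Among reads assigned to single genes, the profile was dominated by a small number of miRNA genes. Reads that match several loci, 48.6% and 52.8% of mapped reads in replicates 1 and 2, were in neither the levels nor the totals. The ranking and the shares below therefore cover assigned reads only. Mir139 (ENSMUSG00000065446.1; mm10 chromosome 7, 101475376 to 101475443, within an intron of the phosphodiesterase gene Pde2a) was the most abundant, at 112556 ± 304 CPM. It took 11.277% of the counts in replicate 1 (95% exact Clopper-Pearson interval 11.237 to 11.317%) and 11.234% in replicate 2 (11.205 to 11.263%). Next came Mirlet7g (71794 ± 4709 CPM), Mirlet7b (60463 ± 4459 CPM), Mir127 (54059.7 ± 5425 CPM) and Mirlet7i (51983 ± 6461 CPM). Mir132, whose transcription follows neuronal activity, reached 49092 CPM with a wide SD of 15979.9 CPM. Mir744, within an intron of the kinase gene Map2k4, was at 35575 ± 1297 CPM. The 10 most abundant genes together held 50.8% ± 4.40 of the counts, the top 20 held 65.2% ± 2.13 and the top 50 held 85.2% ± 1.14. A share of 50% of the counts was reached by 9 genes of replicate 1 and by 11 genes of replicate 2. Of the 20 most abundant genes in each library, 17 were shared, as were 8 of the top 10. At least 10 counts in both libraries were found for 392 genes, which are called measured below, and 761 genes had at least 1 count in either library. The other 1441 genes had no count on their own strand.

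Members of the let-7 family, which restrain proliferation and accumulate as tissues mature, made up the largest of the gene lists. With Mir98 included, its 12 genes held 24.7% ± 3.29 of the counts, and all 12 were measured. Mirlet7g (intron of Wdr82, chromosome 9, 106178840 to 106178927), Mirlet7b (exon of Lncppara, chromosome 15, 85707319 to 85707403) and Mirlet7i (exon of D630033A02Rik, chromosome 10, 122985640 to 122985724) led the list. Mirlet7e (intron of Spaca6) followed at 28648 ± 1000.0 CPM. Mirlet7d was at 25213 CPM with an SD of 14851 CPM, the result of a difference between the libraries that is given further on. The numbered copies ranged from Mirlet7a-2 at 145 ± 69.0 CPM to Mirlet7f-2 at 2464 ± 407 CPM. Reads that match several loci were not assigned to genes in these files, so the raw count of a gene with near-identical copies is a minimum. Its CPM is uncertain in both directions, because the total leaves out such reads too. The median level of the list exceeded that of each of 10000 random lists of the same size in both libraries.

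The imprinted Dlk1-Dio3 domain, whose miRNAs are expressed from the maternal chromosome, held 17.7% ± 0.084 of the counts. Of the 61 symbols listed for it, 59 were in the files and 51 were measured, and 58 of them lay on chromosome 12 between 109563692 and 109747960. Mir127, which lies antisense to the retrotransposon-like gene Rtl1, took 30.5% of the list's counts. Mir487b was at 18848 ± 385 CPM, Mir770, in an exon of the non-coding RNA gene Meg3, at 18489 ± 6019 CPM, and Mir433 at 15279 ± 2099.6 CPM. The list's median level also lay above every random list in both libraries. Its share of counts was 17.805% in replicate 1 and 17.686% in replicate 2.

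**Figure D1:**
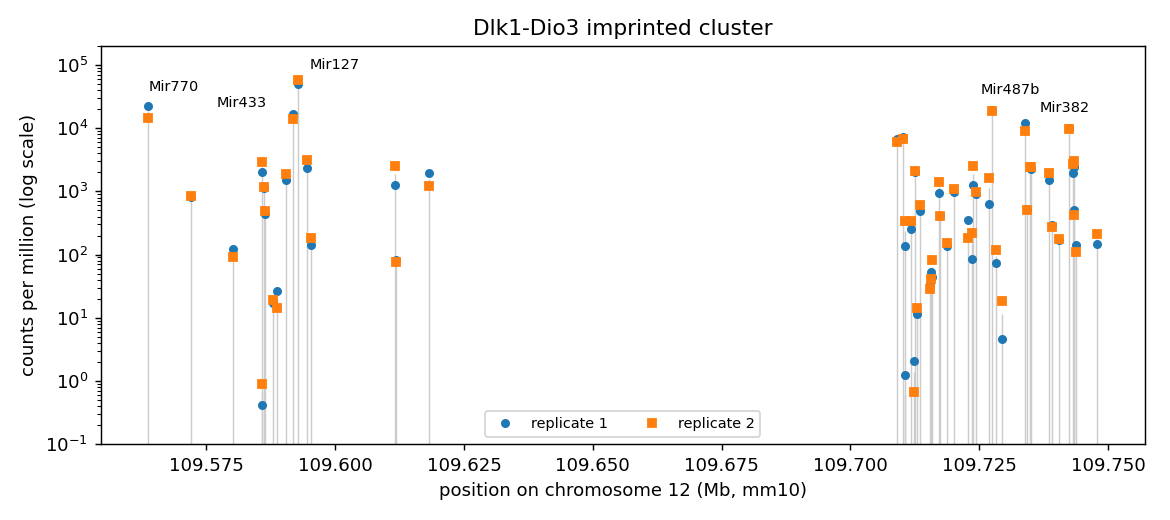
Levels of the miRNA genes of the Dlk1-Dio3 imprinted cluster along chromosome 12 (x axis, position in Mb, mm10) in CPM (y axis, log scale), with circles for replicate 1 and squares for replicate 2. Mir127 stands highest at 54059.7 CPM on average, and 51 genes of the cluster had at least 10 counts in both libraries.

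Lists of miRNAs known from particular cell types were read for what the tissue held. The neuron-enriched list took 10.4% ± 1.04 of the counts (7.64% with numbered copies left out), and Mir132 alone supplied 47.4% of the full list. Mir433, Mir128-1 (14204 ± 4811 CPM, intron of R3hdm1) and Mir137 (7215 ± 1199.9 CPM) followed. Of its 21 genes, 4 (Mir134, Mir433, Mir485 and Mir495) also belong to the Dlk1-Dio3 list. The miR-124 copies on the list summed to only 4.117 CPM. Reads that match several loci were not assigned, so this level and the make-up of the list are uncertain. The astrocyte-enriched list held 4.23% ± 0.904, led by Mir23b (16619 ± 3566 CPM), Mir29a (9251 ± 3814 CPM), Mir23a (7572 ± 1647 CPM) and Mir26b (4911 ± 830 CPM). The endothelial and mural list held 2.24% ± 0.796. Mir126a, the endothelial miRNA in an exon of Egfl7, was at 16643 ± 8288 CPM, and the smooth-muscle miRNAs Mir143 and Mir145a were at 5449 ± 299 and 290.1 ± 31.5 CPM. Median levels of these 3 lists, taken over members with at least 1 count in either library, lay in the upper 2.5% of random lists in both libraries, and 8 of the 24 lists did so. Members with no count were left out of these medians: the endothelial median rests on 3 of 5 genes, and that of the numbered copies on 61 of 143. No list lay in the lower 2.5% in both. Random lists were drawn from all genes with a count, and the 700 of these without numbered copies had a median log2(CPM + 1) of 2.422. The numbered copies themselves ranked at percentiles 99.89 and 99.715 in replicates 1 and 2. A high rank, here or for the let-7 and Dlk1-Dio3 lists, was set against many low genes and does not by itself mark a cell type.

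Lists of other cell types held lower shares. Oligodendrocyte-enriched genes held 0.314% ± 0.059, from Mir219a-2 (1778 ± 612 CPM) and Mir338 (1357 ± 22.5 CPM, intron of Aatk), which both promote oligodendrocyte maturation. Mir219b, annotated on the other strand of Mir219a-2, had 0 counts in both libraries. When the strands were counted together, reads in such loci belonged to no single gene: the oligodendrocyte list then held 0.0001%, the endothelial list 0.622% and the red-cell list 0.0028%. Genes of microglia and white blood cells held 0.240% ± 0.013, led by Mir150 (1427 ± 97.7 CPM) and Mir146 (824 ± 43.6 CPM), while Mir142 and Mir155 stood at 76.3 ± 1.86 and 61.4 ± 13.3 CPM. The choroid plexus and ependyma list held 0.094% ± 0.010, mostly Mir204 (613 ± 149 CPM, intron of Trpm3). Red-cell miRNAs were scarce, with Mir451a at 85.4 ± 3.50 CPM, Mir486 at 27.6 ± 4.12 CPM and 0.014% ± 0.001 for the list. Epithelial and olfactory bulb genes summed to 224 ± 10.5 CPM, with Mir203 at 67.2 ± 18.7 CPM and Mir429 at 62.6 ± 2.05 CPM.

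Lists of foreign tissues and of other regions held low levels. Heart and skeletal muscle genes summed to 42.4 ± 6.13 CPM, of which Mir206 gave 17.8 ± 6.27 CPM. Of the 10 genes on that list, 6 had a count in either library. Mir133b, which shares 21 bases with another locus, had 0 counts in both, so this low sum is uncertain. The liver, pancreas and gut list summed to 103 ± 15.0 CPM, of which the hepatocyte miRNA Mir122 gave 55.8 ± 2.51 CPM. Sensory organ genes reached 22.1 ± 1.12 CPM, and the Hox-cluster genes of hindbrain and spinal cord reached 39.6 ± 0.312 CPM, mostly Mir10b at 31.2 ± 0.965 CPM. The list of pluripotent cells had 6 counts in replicate 1 and 11 in replicate 2 over its 12 genes in the files. The miR-9 list, a family abundant in neural progenitors and neurons, summed to only 96.6 ± 12.2 CPM over Mir9-1, Mir9-2 and Mir9-3, which share 26 to 30 or more bases with another locus, so this level is uncertain.

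**Figure D2:**
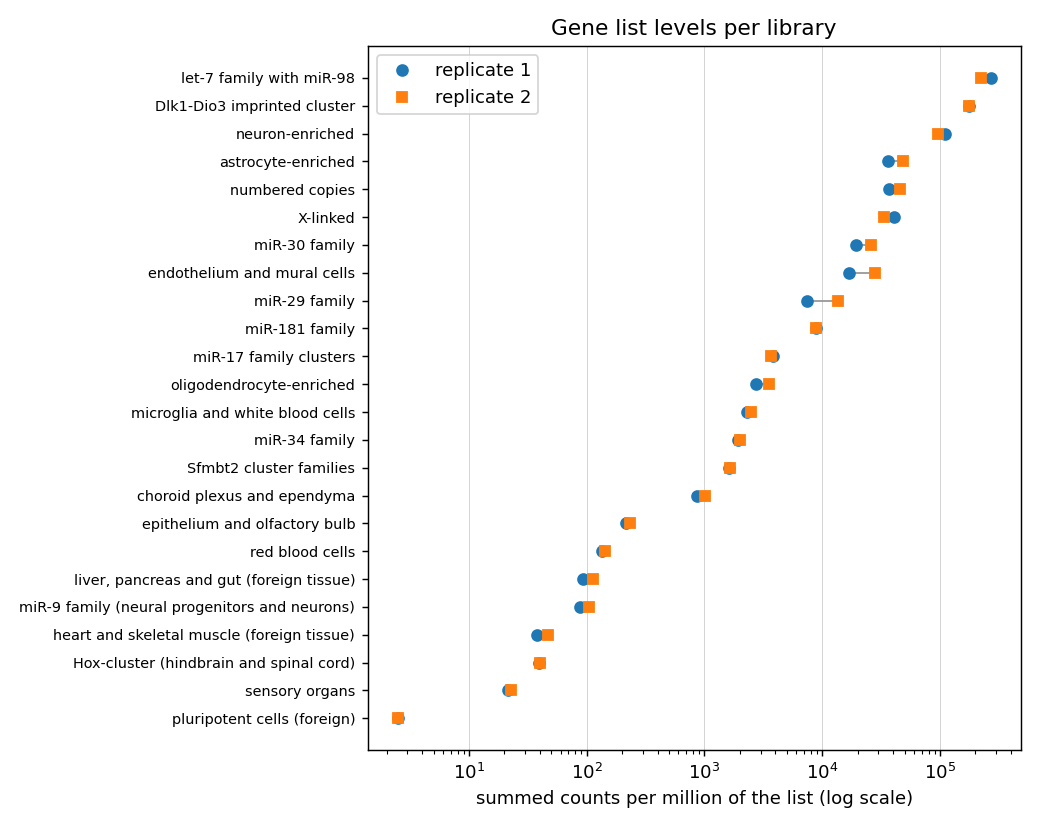
Summed level of each of 24 gene lists (x axis, CPM, log scale) in replicate 1 (circles) and replicate 2 (squares), ordered by mean level. The let-7 and Dlk1-Dio3 lists stand highest, at 24.7% and 17.7% of all counts, and the list of pluripotent cells lowest, with 6 and 11 counts.

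Among the other families, miR-30 held 2.28% ± 0.458, of which Mir30d (12761 ± 2202 CPM) gave 56.0%. The miR-29 family, whose 4 genes are all also in the astrocyte list, held 1.05% ± 0.432, and Mir29a gave 88.3% of it. The miR-181 family held 0.882% ± 0.005, spread over Mir181b-2 (3166 ± 354 CPM), Mir181d (2716 ± 206 CPM) and Mir181c (2336 ± 483 CPM). Without numbered copies the miR-181 share was 0.505% and the oligodendrocyte share 0.136%. The miR-17 family clusters, which promote proliferation, held 0.374% ± 0.010 with Mir93 at 1695 ± 191 CPM. The miR-34 family held 0.196% ± 0.006, mostly the p53-responsive Mir34a at 1674 ± 114 CPM. Genes named after the families of the Sfmbt2 cluster held 0.163% ± 0.002: 13 of their 81 genes had any count, and the 4 most abundant, led by Mir467d at 693 ± 172 CPM, shared at least 30 bases with another locus. The 142 X-linked genes held 3.71% ± 0.509, led by Mir652 at 11511 ± 536 CPM in an intron of Tmem164. All genes with numbered copies together held 4.14% ± 0.601.

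Replicate 2 and replicate 1 ranked the genes alike, with gene-by-gene differences beyond counting error. Mir195a (5.98-fold), Mir99b (4.18-fold), Mir1298 (3.40-fold), Mir22 (3.12-fold) and Mir153 (2.84-fold) were the genes with the highest excess in replicate 2 among those with at least 100 counts in each library that the naming rule covers. Mir222 (3.74-fold), Mirlet7d (2.43-fold), Mir31 (2.14-fold), Mirlet7a-2 (2.02-fold) and Mir298 (1.98-fold) were lower in replicate 2. Between the libraries, log2 ratios (replicate 2 over replicate 1) were 2.58 for Mir195a with a counting SE of 0.032, and −1.90 for Mir222 with an SE of 0.028. Mir301 and Mir26a-1 were singled out after their values were seen. Mir301, in an intron of Ska2 on chromosome 11 (87113004 to 87113089), had 78 counts in replicate 1 and 3156 in replicate 2, a log2 ratio of 4.44 ± 0.165 (counting SE). Mir26a-1, in an intron of Ctdspl on chromosome 9 (119031796 to 119031885), had 396 and 24 counts, a log2 ratio of −4.94 ± 0.303 (counting SE). Mir26a-1 is a numbered copy that shares 25 bases with another locus, and Mirlet7a-2 is one that shares 23. Reads that match several loci were not assigned, so the ratios of these 2 genes rest on the remaining reads and are uncertain.

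Of the 392 measured genes, 223 passed an adjusted p of 0.05 in an exact conditional binomial test (two-sided, Benjamini-Hochberg adjusted), 134 of them higher and 89 lower in replicate 2 (120 and 99 with TMM or DESeq2 scaling). Most differences were small: 284 of the measured genes (72.4%) lay within 1.5-fold. Of the 223 genes past the test, 44 differed by over 2-fold, 32 upward and 12 downward. Across measured genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.982 and Spearman's rho 0.978. For the 242 genes with at least 100 counts in both libraries, log2 ratios had an SD of 0.559, against 0.0765 from counting error alone. Mir139, the most abundant gene, did not pass (log2 ratio −0.006, adjusted p = 0.166 in the exact test), but passed at −0.07 with TMM or DESeq2 scaling. This test compares these libraries, not conditions, and with 1 library per mouse the mouse and the library cannot be separated. When the spread between the libraries (biological coefficient of variation 0.306, edgeR) was allowed for in edgeR's exact test, 3 genes passed its threshold: Mir301, Mir26a-1 and Mir195a. That test sets 1 library against 1 library with a dispersion taken from the same pair, so it ranks the differences and has no replicate check.

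**Figure D3:**
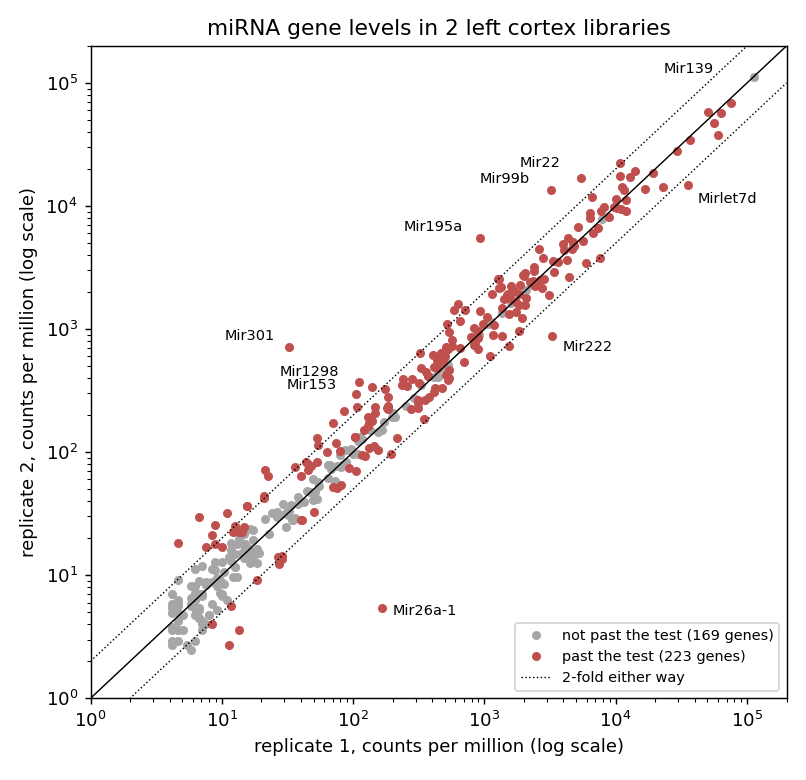
Level of each of the 392 measured miRNA genes in replicate 1 (x axis) and replicate 2 (y axis), both in CPM on log scales, with equality as a solid line and 2-fold differences as dotted lines. The 223 genes past the exact test are coloured apart from the other 169, and Mir301 and Mir26a-1 lie farthest from the line, at log2 ratios of 4.44 and −4.94.

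Few gene lists moved as a whole between the libraries. All 12 let-7 genes were lower in replicate 2 and all 12 passed the test, both over all measured genes and adjusted over the list alone. That test covers counting error only, and none of the 12 was among the 3 genes past edgeR's exact test. Their median log2 ratio was −0.34, at percentile 0.16 of random lists matched on mean level, and the summed counts stood at 0.828 of replicate 1 (exact binomial interval 0.825 to 0.831). Random lists drew each gene independently, while let-7 genes are alike in sequence and some lie in the same host gene. The percentile can therefore overstate how unusual their shift was. In the Sfmbt2 families 6 of 8 measured genes were lower, with a median of −0.36 at percentile 1.36, and 6 passed (5 lower, 1 higher; also 6 adjusted over the list alone). Their summed counts nevertheless gave a ratio of 1.02 (interval 0.982 to 1.06), because Mir467d was higher, at a log2 ratio of 0.51. These were 2 of 21 lists with a percentile outside the central 95%, where chance gives about 5% of lists. Both lists hold genes that share stretches of sequence with other loci. Reads that match several loci, 48.6% of mapped reads in replicate 1 and 52.8% in replicate 2, were not assigned. The shifts of these lists therefore rest on the remaining reads and are uncertain. In the Dlk1-Dio3 list 25 genes were higher and 13 lower past the test (39 in all adjusted over the list alone), and the ratio of summed counts was 0.993 (0.990 to 0.997), against a median of 0.11.

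Other lists held members that went both ways. Of 18 measured neuron-enriched genes, 9 were higher and 6 lower past the test (15 adjusted over the list alone). Their summed ratio of 0.868 and median of 0.13 differed in sign on the log scale. Mir132, the most abundant member, was lower (log2 ratio −0.68), and 11 of the 18 had a log2 ratio above 0, among them Mir128-1 (log2 ratio 0.70). In the endothelial list Mir126a was higher (2.09-fold) while Mir143 and Mir145a were lower (log2 ratios −0.11 and −0.22), so the summed ratio was 1.67 and the median −0.11. Of 11 astrocyte-enriched genes, 5 were higher and 4 lower (11 in all adjusted over the list alone). Within the miR-29 family Mir29a (1.82-fold) and Mir29c (2.00-fold) were higher, and only these 2 passed over all measured genes. All 4 members passed the test adjusted over the list alone, where Mir29b-1 was lower (log2 ratio −0.30). Mir29b-1 and Mir29b-2 are numbered copies that share 25 bases with another locus. Reads that match several loci were not assigned, so the ratios of Mir29b-1 and Mir29b-2 are uncertain. The miR-30 family had 4 higher and 1 lower (6 in all adjusted over the list alone). Oligodendrocyte-enriched genes had a summed ratio of 1.30 and a median of −0.03, as Mir219a-2 was higher (1.64-fold) and Mir338 had a log2 ratio of −0.03 that did not pass, or −0.10 that did with TMM or DESeq2 scaling. Red-cell genes gave 1.08 (exact binomial interval 0.939 to 1.23) and −0.08, and Mir144, 2.35-fold higher, was the only one of the 3 measured to pass. Epithelial genes gave 1.07 (interval 0.961 to 1.19) and −0.32. Both intervals include 1, so neither sum had a clear direction. Of the epithelial genes, 2 were higher past the test, among them Mir200b (3.34-fold), and 2 were lower, Mir200c (2.01-fold) and Mir203 (1.49-fold).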

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

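The test of the shared stretch and the test of genes annotated on both strands were chosen only after the results they bear on were seen. The other tests in this part were fixed before.

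Reads that match several loci are given because they lay outside the gene counts, which they exceeded: 2636677 reads in replicate 1 and 5818669 in replicate 2. The bar for listing them, more than the 3 counts that a value of 0 allows, says nothing about whether their number is unusual, and which loci they match was not analysed here. The copies of miR-9 and miR-124, families abundant in brain in general, together held 100.7 CPM against 60463 CPM for the single-copy Mirlet7b. If uncounted multi-locus reads lowered numbered copies at large, at least 50% of them would have lain below the median of the other genes, but 27.87% of 61 did. The 700 other genes had a median log2(CPM + 1) of only 2.422. Copies that lost reads could still lie above it, so this share cannot decide the question. Among genes numbered below 400 or in the let-7 family the copies were lower, with a median of 5.997 (n = 57), against 8.185 for 157 other genes that share under 20 bases with another locus. The explanation was met in part and stays open, and whether these copies are low in cortex whatever the counting cannot be told apart from it, since 0 of 57 detected numbered copies shared under 20 bases with another locus. Across those 57 copies the level fell as the shared stretch grew (Spearman's rho −0.364, permutation p = 0.0053; Pearson's r −0.428, permutation p = 0.0006; across genes, which are not independent), with a median of 144.6 CPM for 25 copies sharing at most 24 bases and 3.764 CPM for 15 sharing at least 28, which is consistent with only reads that reach past the shared stretch being counted.

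Counts on the strand opposite to the genes, a column not used for levels, were 166739 in replicate 1 (6.53%) and 380429 in replicate 2 (7.88%), listed by the same low bar. A candidate explanation is genes annotated on both strands of a locus, such as Mir219a-2 and Mir219b. Of the opposite-strand counts, 99.95% in replicate 1 and 99.96% in replicate 2 lay in the 64 genes that overlap a miRNA gene on the other strand, and 80 and 142 counts lay elsewhere. For 54 of 55 pairs of gene and library with at least 10 counts, the opposite-strand count and the partner's own-strand count were within 5% of each other. Under the column reading used here, both counts come from largely the same reads. Their agreement therefore follows from the overlap and is no separate support. No biological explanation was tested. With 2 libraries in 1 group, no search for outlying samples or for differences between groups applied.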

How the results depend on the processing

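Leaving numbered copies out of the replicate agreement and of the library comparison was chosen after seeing the data. The number of genes measured was 613 at a minimum of 1 count and 242 at 100 counts, which follows from the filter, and 397 to 460 with a single replicate. Pearson's r between libraries was 0.9863 over all genes with a count and 0.9773 over genes with at least 100 counts, both outside its Fisher interval across genes; the cause was not tested. Genes differing between the libraries numbered 3 under edgeR's exact test, which takes its spread from the same 2 libraries it compares and has no replicate check, and 193 to 232 under the other alternatives. The share of the top 10 genes was 47.7 to 53.9% with a single replicate. The coefficient of variation was 0.265 to 0.310, and the number of high lists 7 to 9. TMM and DESeq2 factors moved all log2 ratios by −0.063 and −0.064, a constant that cannot alter which lists stand apart between libraries, so that result had no alternative that could move it. That shift turned the sign of log2 ratios near 0 that had not passed the test: Mir142 (−0.0130 and −0.0141), Mir10a (−0.0592 and −0.0603), Mir106b (−0.0392 and −0.0403) and, with DESeq2 alone, Mir10b (−0.0008). Of 90 log2 ratios of named genes, 82 and 81 kept their sign and their side of the threshold, 3 passed it (Mir139, Mir338, Mir29b-1) and 2 no longer did (Mir146, Mir192). Of 24 list shares, 13 moved by over 1 SD with both strands together and 14 with totals lacking Mir139, as did 5 of 22 without numbered copies. Leaving a replicate out of a library comparison leaves 1 library and gives no value. No paired analysis was possible because there is 1 group. The filter, not depth alone, limited the main calls to genes with at least 10 counts per library, and 232 genes passed without it.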

Other observations

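All tests in this part except the one on GC content were chosen only after the results they bear on were seen. Genes named here outside the naming rule were chosen after their values were seen.

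Several of the most abundant genes belong to no list of cell types or families. Mir125a (14945 ± 2991 CPM, SD, n = 2), in an exon of Spaca6, and Mir99a (12471 ± 1366 CPM), in an intron of Mir99ahg, are neighbours of let-7 genes. Mir330 (10770 ± 983 CPM; exon of Eml2), Mir191 (10184 ± 1118 CPM), Mir324 (9783 ± 140 CPM; exon of Dvl2), Mir149 (8994 ± 1157 CPM; intron of the glypican gene Gpc1) and Mir151 (8570 ± 547 CPM; intron of the focal adhesion kinase gene Ptk2) followed. Mir674 (7831 ± 32.8 CPM), Mir383 (4881 ± 208 CPM; intron of Sgcz) and Mir342 (4771 ± 88.4 CPM; intron of Evl) had small SDs. By place, intronic miRNA genes held 48.5% ± 0.078 of the counts, exonic genes 30.3% ± 1.07 and intergenic genes 21.2% ± 1.15. The 1021 genes with predicted names starting Gm held 0.045% ± 0.0044, and 5 of them were measured.

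Some neighbouring miRNA genes differed in opposite directions between the libraries. In the Spaca6 transcript, Mir99b had a log2 ratio of 2.06, Mirlet7e −0.07 and Mir125a 0.41. Mir296 was higher in replicate 2 (1.09) and its neighbour Mir298 lower (−0.99). Mir195a (2.58) and Mir497 (0.83) shared a direction but not a size, as did Mir222 (−1.90) and Mir221 (−0.80). In the Dlk1-Dio3 cluster, Mir376b was at 1.36 and the nearby Mir376c at −0.90.

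These log2 ratios spread beyond counting error (SD 0.559 against 0.0765), and 3 candidate explanations are given here. Counting error was run as another test and then left out, and these SDs hold what it compared. Different transcription of the primary transcripts in the mice would move neighbours together, but 81 same-strand pairs within 10 kb differed by 1.171 times as much as random pairs matched on mean count (bootstrap interval 0.937 to 1.418; permutation p = 0.8838), and 59 pairs differed by over 3 counting SE. The rule for reading this test was changed after its value was seen, from the permutation p to the bootstrap interval, and both rules gave the same reading. Successive pairs often share a gene, so the pairs are not independent and the interval can be too narrow. The ratio was 1.188 over the 38 pairs off chromosome 12, so this argues against transcription as the whole cause for genes with such neighbours. GC content of the precursor is argued against too, since removing a linear trend lowered the SD by −0.173%, that is, raised it slightly from 0.5588 to 0.5598 with the lost degree of freedom counted. Steps that depend on the mature sequence stay open: 95 pairs of family members at different loci differed by 0.7917 times as much as random pairs (permutation p = 0.1303), and mouse and library cannot be told apart in this design.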
